A study of Mus musculus with 36 samples.

How the data were processed

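Single microglia of male mice aged 6 months were profiled in cortex and in hippocampus. The mice were transgenics with amyloid deposits, called APP mice here, or wild-type (WT) controls. Per the labels' protocols, cells were released mechanically in the cold, gated by FACS as DAPI-negative, DRAQ5-positive, CD11b-high, CD45-intermediate and either CD11c-negative or CD11c-positive, and collected into multiwell plates. Libraries followed a Smart-seq2-based protocol and were sequenced on an Illumina NextSeq 500. Per the submitters' processing notes, the reads were handled with UMI-tools 0.5.3, aligned with HISAT2 2.1.0 to GRCm38 (mm10) and assigned to genes with featureCounts 1.6.0. The deposited values are raw counts per gene and cell barcode, with no normalization. Whether reads that shared a molecular identifier were merged before counting is not given in the sources used here. Of the non-zero entries 27% were 1, and 35.9% were 20 or more and held 88.8% of all counts, so the counts may be reads rather than molecules. The floor of 3 counts used for groups at 0 therefore covers counting error only.

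Each of 36 libraries held 69 to 80 barcodes, 2660 in all with 65037665 counts, and library totals ran from 956491 to 2340598. Barcodes with at least 200 detected genes and at most 20% mitochondrial counts were kept. This removed 3 barcodes for low gene number and 0 for mitochondrial share, leaving 2657 cells with a median of 19482 counts and 805 genes. Doublets were not called, and no cell type was taken out before summing. No library was a copy of another: 0 of 630 library pairs were identical, and the lowest chi-square per degree of freedom between any pair was 22.4.

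Groups, regions, gates and replicates were taken from the sample titles. The genotype tag of the labels differs from the title in 17 of 36 libraries and gives both genotypes to 6 animals, so it was used only as an alternative grouping. A first number in the titles was taken as a possible library set, and its meaning is not given in the sources used here. Libraries of 1 animal, region and gate were summed, which gave 23 replicates in 6 groups. The groups held 4 replicates each, except CD11c-positive APP hippocampus with 3, named 1-2, 2-3 and 4 in the titles. The names 1-2 and 2-3 may mark pools of animals, and these may share animal 2. Summed replicates held 1037425 to 4484427 counts. Gene symbols and positions came from GENCODE vM21 on GRCm38, which covered 26348 of 26348 gene identifiers.

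Replicate sums were compared with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), using TMM scaling, the filterByExpr gene filter, 1 fit with a mean for each of the 6 groups and 17 residual degrees of freedom, and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The fit tested 14892 genes. The common biological coefficient of variation was 1.37. The median of the values fitted per gene was 0.308 for the 345 genes at 500 CPM (counts scaled to a common library total, TMM-adjusted) or more. It was 0.665 for the 3135 genes between 50 and 500 CPM, and 11412 genes lay below 50 CPM. Levels are mean CPM ± SD over replicates, fold changes are log2 values ± SE, and a fold against a group with 0 counts is a lower bound computed against 3 counts over that group. Summed levels of a list are scaled to the raw library total only, without TMM, and include members that the gene filter removed. The comparisons, the tests, 27 gene lists, the rule for named genes and a set of alternatives were fixed before the data were examined.

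The rule for named genes took Itgax, App, Prnp and 1 further gene in every comparison. For each genotype and gate comparison it took the 12 genes that rose and the 8 that fell with the largest fold change among genes past adjusted p 0.05. Such genes had a mean of at least 50 CPM in the higher group and replicate values that did not overlap between the groups, and predicted gene models, mitochondrial genes and ribosomal protein genes were left out of this part. The same rule gave 6 and 6 genes for the region comparisons and for CD11c-positive APP against WT cells, and the 5 smallest p values were taken for interactions. Each list added up to 4 members with the highest mean CPM and up to 2 with the smallest p. Folds are printed for a part of these genes only, 187 pairs of gene and comparison, and this choice was made after their values and the alternatives had been seen. Genes not past the threshold whose sign changed between settings were left out of it, except Ctsb at the hippocampal gate and Lpl in the cortical genotype comparison. Some results of genes under this rule are not reported here.

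The 27 lists covered homeostatic microglia, 2 lists of disease-associated microglia (DAM core, genes with a low baseline, and DAM broad, the early and lysosomal part), interferon response, MHC class I, MHC class II, cell cycle, immediate early genes, inflammatory cytokines and chemokines, lysosome, lipid handling, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, complement and orthologues of Alzheimer risk genes. The remaining lists were markers of border-associated macrophages, monocytes, dendritic cells, neutrophils, lymphocytes, neurons, astrocytes, oligodendrocytes, endothelial cells and red blood cells. No neutrophil marker passed the gene filter, so 26 lists were tested. Several genes stand in more than 1 list, and Itgax stands in none. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison.

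Shares of cells were computed per replicate after each cell was thinned to 1000 counts, which left out 1 cell, and compared with 2-sided exact permutation tests. The smallest p such a test can give is 0.0286 both for 4 against 4 and for 3 against 4 replicates. The tests take replicates as independent, also where both gates come from the same animals. Cells were clustered with scanpy 1.11.5 (2000 variable genes, 20 principal components, 15 neighbours, Leiden resolution 0.8 with leidenalg 0.10.2) in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Figures were drawn with matplotlib 3.10.9.

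The titles give replicate numbers. For cortex CD11c-negative and CD11c-positive cells, and for the regions, the same number names the same animal, whereas WT and APP mice share numbers only. Correlations of the residuals between samples with the same number ran from −0.061 to 0.072 and were 0.045 to 0.072 for the cortical gates. Between the cortical gates the same animal was the closest match for replicates 2, 3 and 4 and not for replicate 1. The main fit had been planned beforehand without the animal, so these correlations were not the reason for that choice. The animal was tried as a block in 2-group fits and as a random effect with limma voom. No blocked 2-group fit was made with CD11c-positive hippocampal cells, whose titles name pools, or for the interactions.

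The alternatives planned beforehand were RLE scaling, no gene filter, DESeq2 1.42.0, a stricter and an absent cell filter, thinned cells, sums without cells carrying other cell types' markers, 2-group fits, blocks, the genotype tag and leaving out each replicate. Cells carrying such markers had at least 3 counts of 1 marker list other than that of dendritic cells, or no count of the microglial lists. They were 1239 of the 2657 kept cells, and a cut at 50 counts marked 426. Alternatives added after seeing the data were counts under 5 set to 0, equal weight per cell, sums without cells holding at least 50 counts of other cell types' markers, the number of cells with 5 counts in place of counts, sums without the clusters led by other cell types' markers, genes per cell as a covariate and removal of a trend over exon length. For genotype and gate the lists were tested again with camera under the last 3 of these.

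The tests were tested on simulated data with the depth and spread of these samples and 50 genes changed at each of 4 fold sizes from 2 to 16. Counts were drawn independently per gene from negative binomial distributions with the dispersions edgeR had fitted, so edgeR was judged under its own model. Numbers of false calls, of edgeR as of the other tests, may therefore differ in the real counts. The edgeR test made 0 false calls, except 1 each where hippocampal CD11c-positive cells were compared with APP and with WT CD11c-negative cells. At a 4-fold change it recovered 0%, 4%, 8% and 4% of the genes in the genotype comparisons of cortex and hippocampus and the gate comparisons of cortex and hippocampus. At a 16-fold change it recovered 14%, 20%, 30% and 12%. In the cortical genotype comparison it found 63.6% of the 11 genes with a 16-fold change and at least 50 CPM. DESeq2 made 76, 80 and 152 false calls in the genotype comparison of cortex and the gate comparisons of cortex and hippocampus, and limma voom made 2, 8 and 8.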

Results

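Microglia, the resident macrophages of the brain, were sorted from APP mice, which carry transgenes that make them deposit amyloid, and from WT controls. Itgax encodes CD11c, an integrin carried by a subset of microglia found around amyloid plaques. The sort gave 6 groups: CD11c-negative cells of WT and APP mice and CD11c-positive cells of APP mice, each from cortex and hippocampus. WT cortex held 390 cells in 4 replicates of 1570266 to 3707275 counts, and WT hippocampus 438 cells in 4 replicates of 1811995 to 3966045 counts. CD11c-negative APP cortex held 454 cells in 4 replicates of 1037425 to 4406184 counts, and its hippocampal counterpart 426 cells in 4 replicates of 1127618 to 3576536 counts. CD11c-positive APP cortex held 587 cells in 4 replicates of 3404089 to 4484427 counts, and CD11c-positive APP hippocampus 362 cells in 3 replicates of 1423625 to 4451474 counts. Levels are mean CPM ± SD over replicates, changes are log2 fold changes ± SE, and adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14892 genes unless another test is named. Levels of a whole list are summed CPM without TMM scaling, unlike those of single genes. In every group n = 4, except n = 3 for CD11c-positive APP hippocampus.

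The gene of the sort followed the gate. Itgax (chromosome 7, 128129547 to 128150657 on GRCm38) stood at 159 ± 50.5 CPM in CD11c-positive and 1.245 ± 1.94 CPM in CD11c-negative APP cortex, and at 0 CPM in WT cortex. In hippocampus it stood at 76.0 ± 10.4 CPM in CD11c-positive and 8.73 ± 15.4 CPM in CD11c-negative APP cells, and at 0.916 ± 1.83 CPM in WT cells. A count of Itgax was present in 17.2% of CD11c-positive cortical and 12.98% of CD11c-positive hippocampal cells. It passed the threshold in CD11c-positive APP against WT cortex, where it was at least 543-fold higher (edgeR adjusted p = 0.0143). Between the gates it did not pass in cortex (adjusted p = 0.0779) or hippocampus (adjusted p = 0.493). App stood at 142, 124 and 159 CPM in WT, CD11c-negative APP and CD11c-positive APP cortex and at 46.7, 88.7 and 87.2 CPM in the same groups of hippocampus. Prnp (chromosome 2, 131909928 to 131938429), whose promoter drives the transgenes of this strain, stood at 51.0, 156 and 279 CPM in cortex and at 0.423, 31.7 and 10.003 CPM in hippocampus.

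The first question was how CD11c-positive microglia of APP mice differ from their CD11c-negative neighbours, asked first in cortex. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), which encodes the lipid carrier apolipoprotein E, rose from 408 ± 227 to 4666 ± 463 CPM, a log2 fold change of 3.52 ± 0.54 (n = 4 and 4, edgeR adjusted p = 0.000399). A count of Apoe was present in 583 of 587 CD11c-positive and 173 of 454 CD11c-negative cells. Cst7 (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944), a cystatin that inhibits lysosomal cathepsins, rose from 10.01 ± 17.2 to 1029 ± 65.4 CPM (6.87 ± 1.58, adjusted p = 0.0246). Igf1 (chromosome 10, 87858265 to 87937042), a growth factor, rose from 1.75 ± 2.94 to 281 ± 67.0 CPM (7.70 ± 1.57, adjusted p = 0.0088). In the other direction Tmem119 (ENSMUSG00000054675, chromosome 5, 113793729 to 113800516), a marker of resident microglia, fell from 1663 ± 216 to 417 ± 19.6 CPM (−1.995 ± 0.149, adjusted p = 8.58e-09). Sema4b (ENSMUSG00000030539, chromosome 7, 80186841 to 80226527), a semaphorin, fell from 1323 ± 109 to 160 ± 37.3 CPM (−3.04 ± 0.20, adjusted p = 6.39e-10). The purinergic receptor gene P2ry12 fell from 1862 ± 287 to 736 ± 79.5 CPM (−1.34 ± 0.16, adjusted p = 1.53e-05). In all 78 genes rose and 105 fell, and the median size of a called change was 1.39. In this comparison 1797 genes lay at an unadjusted p under 0.05 where 745 would by chance.

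**Figure D1:**
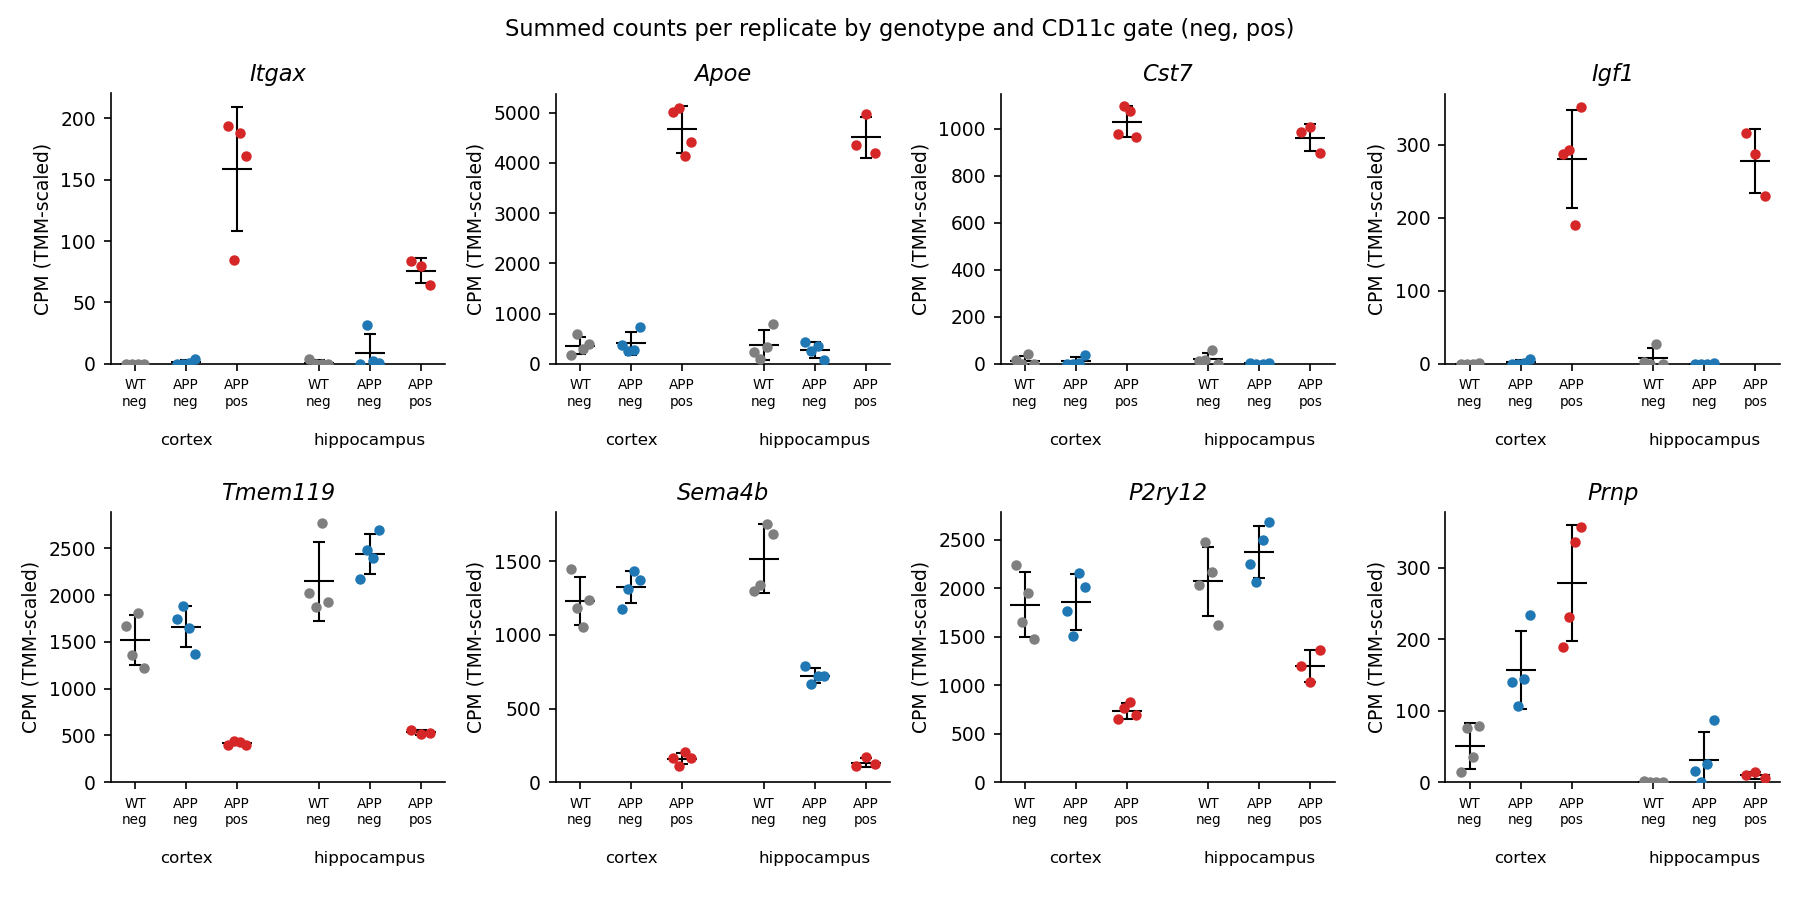
Levels of 8 named genes in TMM-scaled CPM for the 6 groups, with 1 point per replicate, a line at the group mean and error bars for the SD. In both regions every CD11c-positive replicate lies above every CD11c-negative one for Itgax, Apoe, Cst7 and Igf1, and below for Tmem119, Sema4b and P2ry12.

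Genes of the disease-associated microglia program rose with the gate in cortex. Of the 16 tested DAM core members 6 rose and 0 fell, and 14 rose when adjusted over the list alone. Their median log2 fold change was 4.17, and camera gave an adjusted p of 1.96e-16. Beside Cst7 and Igf1, the called members were the chemokine gene Ccl6 (3.05 ± 0.66), the cholesterol 25-hydroxylase gene Ch25h (7.88 ± 1.78), the protease inhibitor gene Serpine2 (1.61 ± 0.24) and the adhesion gene Cadm1 (1.95 ± 0.46). In DAM broad 14 of 20 members rose and 0 fell, and 18 rose when adjusted over the list alone. The median was 1.33, and camera gave an adjusted p of 1.58e-28. Its called members held the tetraspanin gene Cd63 (1.97 ± 0.20, adjusted p = 3.44e-06), the iron storage gene Fth1 (1.40 ± 0.19), and the lysosomal protease genes Ctsb (1.17 ± 0.17) and Ctsz (1.01 ± 0.16). They also held the antigen presentation gene B2m (0.90 ± 0.15), the lysozyme gene Lyz2 (3.95 ± 1.004, adjusted p = 0.0497), Cd52 (4.54 ± 1.11) and the lipid receptor gene Trem2 (0.74 ± 0.17, adjusted p = 0.0286). Of 23 homeostatic genes 11 fell and 0 rose, and 18 fell when adjusted over the list alone. The median was −0.89, and camera gave an adjusted p of 1.77e-31. Among them were Selplg (−0.84 ± 0.11), the receptor gene Csf1r (−0.80 ± 0.18, adjusted p = 0.0235) and the crystallin gene Crybb1 (−3.76 ± 0.65), whereas Cst3 did not pass (−0.21 ± 0.08, adjusted p = 0.3).

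Metabolic and lysosomal lists shifted upward in cortical CD11c-positive cells. For lysosomal genes 8 of 27 rose and 1 fell, 15 and 1 when adjusted over the list alone, with a median of 0.86 and a camera adjusted p of 2.26e-08, or 0.171 without the gene length trend. Examples were the cholesterol transporter gene Npc2 (2.17 ± 0.36), Ctsd (0.86 ± 0.14) and Gm2a (0.74 ± 0.17). For lipid handling 3 of 16 rose and 0 fell, 6 when adjusted over the list alone (median 1.66, camera adjusted p = 3.06e-07). Soat1, which esterifies cholesterol, did not pass (0.77 ± 0.26, adjusted p = 0.22). For cholesterol synthesis 1 of 19 rose, 2 when adjusted over the list alone (median 1.502, camera adjusted p = 0.00195). This was the sterol sensor gene Insig1 (1.55 ± 0.29). For glycolysis and hypoxia 2 of 18 rose, 3 when adjusted over the list alone (median 1.16, camera adjusted p = 1.7e-05). They were the pyruvate kinase gene Pkm (2.14 ± 0.40) and the glucose transporter gene Slc2a1, at least 159-fold higher. For oxidative phosphorylation 1 of 22 rose, 8 when adjusted over the list alone (median 1.19, camera adjusted p = 6.72e-07), namely the complex I gene Ndufa1 (1.73 ± 0.43). Of 85 cytosolic ribosomal protein genes 14 rose and 0 fell, 35 when adjusted over the list alone (median 1.27, camera adjusted p = 3.35e-26), with Rpl41 at 1.79 ± 0.33 and Rps25 at 1.16 ± 0.23. Inflammatory genes had 0 of 17 members past the threshold, also over the list alone (median 1.31, camera adjusted p = 0.0213, 0.0647 without the gene length trend and 0.0857 with genes per cell as a covariate). The cell cycle list had 0 of 18, 1 over the list alone (median 1.24, camera adjusted p = 0.00239, 0.415 with genes per cell as a covariate, adjusted p = 0.165 with an estimated correlation). The other 10 of the 11 lists called by camera also passed with an estimated correlation. When the number of cells with at least 5 counts was tested in place of counts, Ctsb, Ctsd and Gm2a had the opposite sign.

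Lists that did not pass camera in cortex were interferon response (adjusted p = 0.148), MHC class I (0.258), MHC class II (0.258), immediate early genes (0.92), complement (0.803) and Alzheimer risk orthologues (0.92). Of the risk genes 3 rose and 2 fell, Adam10, which encodes an amyloid precursor protein alpha-secretase, among the latter (−0.68 ± 0.14, adjusted p = 0.00959). Markers of border-associated macrophages (0.258), monocytes (0.519), dendritic cells (0.92), lymphocytes (0.92), neurons (0.803), astrocytes (0.438), oligodendrocytes (0.183), endothelial cells (0.0849) and red blood cells (0.854) did not pass either, and no neutrophil marker was tested. In a fit of only these 2 groups with the animal as block, which the titles pair across the gates, camera also called the astrocyte (adjusted p = 0.0167) and oligodendrocyte lists (adjusted p = 0.0479). This fit called 271 genes, against 434 without the block. Further large changes were Nenf, a secreted neurotrophic factor gene, with 909 counts against 1, Hacd2 (2.92 ± 0.63), Pgd of the pentose phosphate pathway (2.99 ± 0.76), Ndufa6 (2.84 ± 0.60) and Cd34 (2.64 ± 0.56). Genes that fell included Cmtm7 (−2.88 ± 0.54), Txlng (−2.81 ± 0.68), Tm6sf1 (−2.76 ± 0.54), Mtss1 (−2.63 ± 0.60), Oma1 (−2.23 ± 0.50) and the mannose phosphate isomerase gene Mpi (−2.19 ± 0.55). The count of 183 called genes fell to 68 without cells carrying other cell types' markers and to 39 with genes per cell as a covariate. The first setting removed 1239 of the 2657 cells of all groups. With the covariate the 183 genes kept their median size (1.39 to 1.40), while the median SE rose from 0.261 to 0.371. CD11c-positive cells held more detected genes per cell at equal depth (467 ± 46.4 against 345 ± 45.0) and a higher mitochondrial share (2.49 ± 0.421% against 1.20 ± 0.296%), each with p = 0.0286 by an exact permutation test. That test does not allow for the pairing of the gates by animal.

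The same question was asked in hippocampus, where CD11c-positive cells again differed by Apoe, Cst7 and homeostatic genes. Apoe rose from 274 ± 158 to 4509 ± 414 CPM (4.04 ± 0.56, n = 3 and 4, edgeR adjusted p = 0.000369), with a count in 361 of 362 CD11c-positive and 151 of 426 CD11c-negative cells. Cst7 rose from 1.88 ± 2.42 to 961 ± 58.4 CPM (8.89 ± 1.76, adjusted p = 0.0127). The lipoprotein lipase gene Lpl rose from 4.91 ± 6.46 to 849 ± 252 CPM (7.33 ± 1.39, adjusted p = 0.0116). Igf1 rose to 278 ± 44.4 CPM, with 2650 counts against 1 (adjusted p = 0.00392). Tmem119 fell from 2438 ± 215 to 532 ± 23.2 CPM (−2.20 ± 0.17, adjusted p = 2.59e-08). Sema4b fell from 724 ± 49.8 to 134 ± 31.9 CPM (−2.43 ± 0.21, adjusted p = 2.4e-07) and P2ry12 by 0.99 ± 0.17 on the log2 scale (adjusted p = 0.00392). In all 66 genes rose and 16 fell, 1626 lay at an unadjusted p under 0.05, and the median size of a called change was 1.71. Further large changes were Gas7, which links membranes to actin (9.93 ± 1.36, 4216 counts against 5), the sulfotransferase gene Chst2 (6.96 ± 1.38) and Akap5 (4.49 ± 1.04). Genes at 0 in CD11c-negative cells were the interferon-induced Ifi27l2a (at least 460-fold higher), the lysosomal GTPase gene Rab7b (at least 327-fold) and Etl4 (at least 217-fold). Falling genes included the adhesion receptor gene Adgrg1 (−2.57 ± 0.45), Susd3 (−2.14 ± 0.34), the histone demethylase gene Kdm6b (−1.78 ± 0.27), Tmem173, which encodes the DNA sensing adaptor STING (−2.19 ± 0.50), and Camk2n1 (−3.31 ± 0.66).

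The DAM, homeostatic and metabolic lists passed camera in hippocampus too. DAM core had 5 of 16 members higher and 0 lower, 13 and 0 when adjusted over the list alone. Its median was 4.85, or 4.80 with members at 0 set to their bound, with a camera adjusted p of 3.04e-24. DAM broad had 9 of 20 higher and 0 lower, 14 and 0 over the list alone (median 1.13, camera adjusted p = 3.04e-24). Among these were Cd63 (1.86 ± 0.21), B2m (1.09 ± 0.16) and Ctsz (0.90 ± 0.17). Ctsb (0.74 ± 0.18, adjusted p = 0.0591) and Trem2 (0.52 ± 0.18, adjusted p = 0.281) did not pass. Ctsz and Ctsb had the opposite sign by the number of cells with at least 5 counts. Homeostatic genes had 5 of 23 lower and 0 higher, 11 and 0 over the list alone (median −0.70, camera adjusted p = 3.06e-20). Selplg (−0.90 ± 0.12) and the fructose transporter gene Slc2a5 (−1.83 ± 0.32) were among them. Lipid handling had 5 of 16 higher, 10 over the list alone (median 1.79, camera adjusted p = 4.64e-14), with Soat1 at 1.70 ± 0.28 and Ch25h at 861 counts against 1. Lysosomal genes had 4 of 27 higher and 0 lower, 8 and 1 over the list alone (median 0.55, camera adjusted p = 1.61e-06), with Gm2a at 1.37 ± 0.18 and Npc2 at 1.87 ± 0.37. Cholesterol synthesis had 1 of 19 higher, 3 over the list alone (median 1.43, camera adjusted p = 7.98e-05), which was Insig1 (2.72 ± 0.31, adjusted p = 2.51e-05). Oxidative phosphorylation had 1 of 22 higher, 4 over the list alone (median 0.84, camera adjusted p = 8.07e-08). Glycolysis had 0 of 18 higher, 1 over the list alone (median 1.11, or 1.21 over the 16 members with more than 3 counts in a group, camera adjusted p = 0.000197). Ribosomal proteins had 7 of 85 higher, 18 over the list alone (median 1.04, camera adjusted p = 3.26e-22).

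Immune lists also passed camera in hippocampus. Interferon genes had 1 of 22 members higher, 8 over the list alone (median 2.77, camera adjusted p = 1.64e-07). MHC class I had 1 of 13, 2 over the list alone (median 0.66, adjusted p = 0.0156, 0.0996 without the gene length trend), and inflammatory genes 0 of 17, 5 over the list alone (median 1.70, adjusted p = 0.000227). MHC class II had 0 of 9, 5 over the list alone (median 2.47, adjusted p = 0.00026, adjusted p = 0.0653 with an estimated correlation). The cell cycle list had 0 of 18, 2 over the list alone (median 0.63, adjusted p = 0.00368, 0.537 with genes per cell as a covariate, adjusted p = 0.138 with an estimated correlation). Monocyte markers had 0 of 5, 3 over the list alone (median 3.93, adjusted p = 0.0203, 0.226 with genes per cell as a covariate). With that covariate the monocyte median was 4.20 and that of the cell cycle list −2.15. In clustering, 18 cells were led by MHC class II genes, of which 11 were hippocampal CD11c-positive and 0 hippocampal CD11c-negative APP cells. Without these and a cluster led by neural genes, interferon, MHC class I, MHC class II and inflammatory genes passed camera (adjusted p = 1.82e-05, 0.0473, 0.00509 and 0.000561), and monocyte markers did not (0.0616). The immediate early, complement and Alzheimer risk lists and the other markers did not pass. Of the 15 lists past camera 13 also passed with an estimated correlation. The first number in the titles, whose meaning is not given in the sources used here, was taken as a possible library set, and it differs between the gates in hippocampus. For genes not also called in cortex a difference between such sets cannot be told apart from the gate. Both gates share these numbers in cortex, where 96.3% of the 82 genes had the same sign. The count of 82 called genes was 12 without cells carrying other cell types' markers and 24 with genes per cell as a covariate. With the covariate the median size of the 82 did not shrink (1.71 to 1.81), while the median SE rose from 0.300 to 0.415. RLE scaling gave 41 higher and 37 lower genes.

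**Figure D2:**
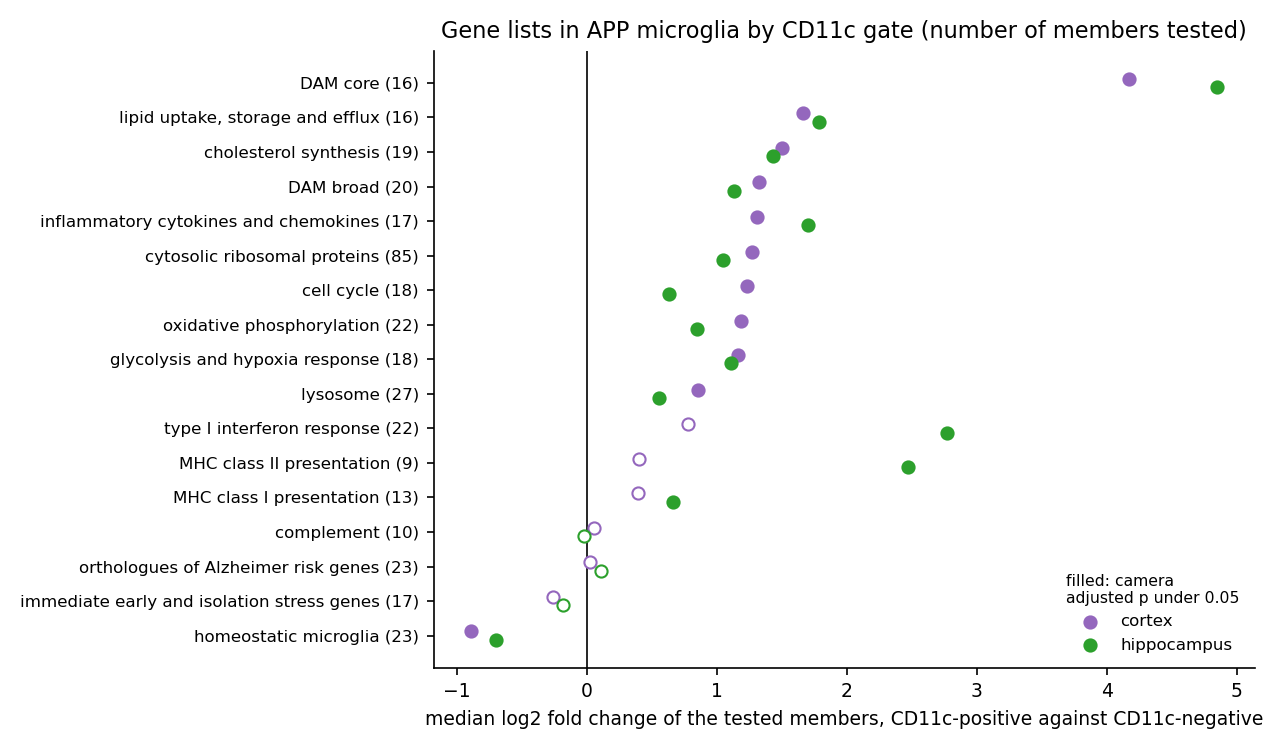
Median log2 fold change of the tested members of the 17 lists other than markers of other cell types, CD11c-positive against CD11c-negative APP cells, in cortex and hippocampus, with the number of members in brackets. Filled points mark a camera adjusted p under 0.05, and the DAM core medians of 4.17 and 4.85 lie farthest from 0 among the plotted lists.

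Whether the gate acted differently in the regions was tested as an interaction. No gene passed by edgeR, with 1116 at an unadjusted p under 0.05, while DESeq2 called 248 and limma voom 18. The smallest p values belonged to Camk2n1 (−4.19 ± 0.84), Adam10 (0.99 ± 0.20), Kmt2d (0.78 ± 0.17) and Gas7 (7.02 ± 1.52), each with an adjusted p of 0.315, and to Zfhx3 (1.26 ± 0.29, adjusted p = 0.372). Across the 3480 genes with at least 50 CPM the gate effects of cortex and hippocampus correlated at a Pearson r of 0.540, computed over genes, which are not independent replicates. Of the called genes 36 were higher in both regions and 12 were lower in both. Chance would give 0.346 and 0.113 if every tested gene were equally likely to be called. No chance value matched for gene level was computed. The number changed in opposite directions was 0. The interferon list was the single one past camera (adjusted p = 0.00726, adjusted p = 0.316 with an estimated correlation).

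The second question was whether microglia outside the CD11c gate differ between APP and WT mice. In cortex no gene passed edgeR's test, 1354 genes lay at an unadjusted p under 0.05, and DESeq2 called 245 and limma voom 19. Lpl was present in 32 of 454 CD11c-negative APP cells and in 0 WT cells, at 59.5 ± 46.7 against 0 CPM, with 39.2% of its counts in 1 cell and the opposite sign when grouped by the genotype tag (adjusted p = 0.402). Prnp stood at 156 ± 54.6 against 51.0 ± 31.8 CPM (1.62 ± 0.93, adjusted p = 0.708). The lipid droplet gene Plin2 had 242 counts against 1, the interferon-induced Ifi27l2a 195 against 1, and Ifitm3 357 against 0, each with an adjusted p of 0.519. Homeostatic genes stood at 25572 ± 1286 CPM in APP and 25587 ± 2914 CPM in WT cells, and DAM core genes at 997 ± 299 and 1124 ± 261 CPM. Camera called DAM broad (adjusted p = 0.032, adjusted p = 0.647 with an estimated correlation), interferon (0.0265, adjusted p = 0.556 with an estimated correlation), MHC class II (0.032, adjusted p = 0.647 with an estimated correlation) and cell cycle (0.032, adjusted p = 0.647 with an estimated correlation). No member of these passed over all genes. When adjusted over the list alone 4 interferon, 2 MHC class II and 1 cell cycle gene were higher, and fry and the 2-group fit with replicate number as block called 0 lists. With genes per cell as a covariate camera no longer called DAM broad, interferon and MHC class II (adjusted p = 0.121, 0.077 and 0.168), and without clusters led by neural and MHC class II genes it did not call DAM broad, interferon and cell cycle (0.155, 0.11 and 0.155). The medians of these lists stayed above 0. With the covariate they were 0.193, 1.62 and 1.15, against 0.146, 1.545 and 1.37 in the main fit. Without those clusters they were 0.123, 2.17 and 2.03, where cell cycle had 2.07 in the main fit. In simulated data of this comparison the same test found 0 of 50 genes with an 8-fold change, 8 of which had at least 50 CPM, and 63.6% of the 11 genes at that level with a 16-fold change.

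In hippocampus 49 genes rose and 177 fell in CD11c-negative APP against WT cells. Insig1 (ENSMUSG00000045294, chromosome 5, 28071363 to 28078662), a sensor that restrains cholesterol synthesis, fell from 509 ± 143 to 110 ± 30.4 CPM (−2.21 ± 0.30, n = 4 and 4, edgeR adjusted p = 9.02e-05). Abcg1 (ENSMUSG00000024030, chromosome 17, 31057675 to 31117988), a cholesterol exporter, fell from 4601 ± 380 to 2190 ± 123 CPM (−1.07 ± 0.16, adjusted p = 0.000212). Gm2a, the activator of lysosomal ganglioside breakdown, fell from 2964 ± 439 to 1299 ± 165 CPM (−1.19 ± 0.17, adjusted p = 0.000159). Adam10 fell by 0.84 ± 0.14 (adjusted p = 0.000802) and the endocytic adaptor gene Picalm by 0.70 ± 0.15 (adjusted p = 0.0145) on the log2 scale. Sept10, a septin gene, fell from 1164 ± 195 to 264 ± 141 CPM (−2.14 ± 0.30). Fth1 rose (0.94 ± 0.18, adjusted p = 0.00459), as did Rps9 (1.22 ± 0.31), while Rps25 fell (−0.93 ± 0.23). Elf2 (ENSMUSG00000037174, chromosome 3, 51252720 to 51340663), a transcription factor gene, rose to 107 ± 24.1 CPM with 1144 counts in 46 cells against 1 count in WT cells (adjusted p = 6.16e-05).

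Many of the largest rises in hippocampus rested on few cells. Qars, a glutamine tRNA ligase gene (7.16 ± 1.25, adjusted p = 0.00118), was present in 24 of 426 APP and 4 of 438 WT cells. Pigq (at least 149-fold higher) was present in 23 and 0 cells, and Hint3 (at least 154-fold) in 14 and 0 cells. Other genes that rose were Mtf2 (6.84 ± 1.48), Prkacb (6.88 ± 1.54), Tmod3 (4.67 ± 1.05), C1qbp (4.76 ± 1.24) and Adprh (3.39 ± 0.87). Slc2a8, Med22, Lrif1 and Cyp51 rose with 781, 645, 420 and 294 counts against 2, 3, 2 and 1. Prnp rose (5.79 ± 1.21, adjusted p = 0.00705) with counts in 7 APP and 4 WT cells, and its replicate values overlapped. Falling genes included Ttyh2 (−2.93 ± 0.72), Rcor3 (−2.47 ± 0.59), Tmem263 (−2.31 ± 0.51), the glycine cleavage gene Amt (−2.28 ± 0.54), Zfp317 (−2.15 ± 0.46) and Zfp862-ps (−1.95 ± 0.32). The median size of a called change was 1.20, and 2353 genes lay at an unadjusted p under 0.05.

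No list passed camera in this hippocampal comparison, while fry called ribosomal proteins (adjusted p = 0.00806), complement (0.0232) and glycolysis (0.0251) upward. Members past the threshold were 1 higher in DAM broad, 1 lower in lysosome, 1 lower in lipid handling, 1 higher and 1 lower in cholesterol synthesis, 1 higher and 1 lower in ribosomal proteins, 1 higher in complement and 2 lower in the Alzheimer risk list. Homeostatic genes stood at 36266 ± 807 CPM in APP and 29987 ± 1245 CPM in WT cells, and DAM core genes at 1484 ± 204 and 1362 ± 335 CPM. At equal depth APP cells had more detected genes per cell (375 ± 19.3 against 292 ± 13.996, p = 0.0286) and a higher mitochondrial share (1.18 ± 0.104% against 0.665 ± 0.0683%, p = 0.0286, both by exact permutation tests). The first number in the titles parts the libraries of both regions by genotype, so a difference between possible library sets cannot be told apart from genotype. Grouping by the genotype tag gave 0 called genes, with the opposite sign for Qars and Picalm. That fit held only the hippocampal CD11c-negative libraries and put those of WT replicate 1 into both groups. It compares with the 2-group fit by title below rather than with the 226. Without cells carrying other cell types' markers 84 were called. A fit of only these 2 groups called 99 genes, and 69 with replicate number as block.

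**Figure D3:**
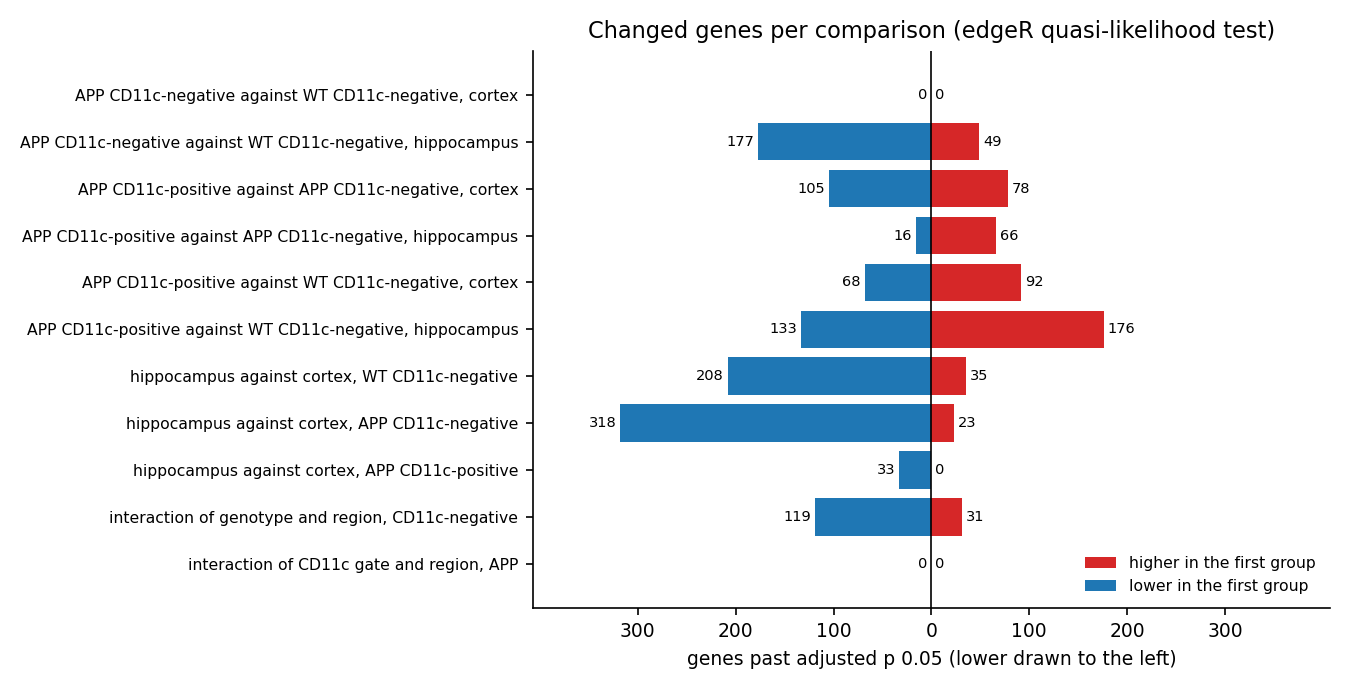
Number of genes past an adjusted p of 0.05 in each comparison by edgeR's quasi-likelihood test, with genes lower in the first group drawn to the left and higher ones to the right. CD11c-negative APP against WT cells gave 0 genes in cortex and 226 in hippocampus.

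Whether genotype acted differently in the regions was tested as an interaction in CD11c-negative cells. There 31 genes were higher and 119 lower in the hippocampal than in the cortical effect. The smallest p values belonged to Dpysl2, a regulator of axon growth (−1.27 ± 0.15, edgeR adjusted p = 0.00022), and the histone methyltransferase gene Kmt2d (−1.24 ± 0.16, adjusted p = 0.00038). Next were the cytoskeletal gene Tacc1 (−1.37 ± 0.19), the replication gene Mcmbp (−1.76 ± 0.25) and Skil, a repressor of TGF-beta signalling (−1.53 ± 0.22). No list passed camera, with an estimated correlation or with fry. With genes per cell as a covariate 0 genes were called, and without cells carrying other cell types' markers 52 were.

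The third question, how CD11c-positive APP cells compare with WT microglia, gave 92 higher and 68 lower genes in cortex and 176 higher and 133 lower genes in hippocampus. Apoe rose by a log2 fold change of 3.69 ± 0.54 in cortex (n = 4 and 4, edgeR adjusted p = 0.000266) and 3.62 ± 0.55 in hippocampus (n = 3 and 4, adjusted p = 0.000416). Sema4b fell by 2.94 ± 0.19 and 3.50 ± 0.22 on the log2 scale (adjusted p = 1.26e-09 and 6.39e-10). In cortex Lpl (at least 2167-fold), Ch25h (at least 370-fold) and Rab7b (at least 224-fold) were higher, as were Igf1 (4128 counts against 1) and Ifi27l2a (1251 against 1). Crybb1 (−3.62 ± 0.64), Oma1 (−2.49 ± 0.51), Cmtm7 (−2.39 ± 0.52) and the cytokine gene Il16 (−2.37 ± 0.57) fell. In hippocampus the pattern recognition receptor gene Clec7a was higher (2874 counts against 1), as were Ifitm3 (at least 247-fold), Commd1 (at least 241-fold), Tmem242 (at least 177-fold), Fxyd5 (at least 164-fold) and Zfp35 (at least 163-fold). Cass4 (−3.85 ± 0.91), Mxd4 (−2.82 ± 0.74), Zfp217 (−2.74 ± 0.69) and Kdm6b (−2.65 ± 0.28) fell, and Pgbd1 had 2 counts against 1298. Camera called 13 lists in cortex, 12 of them upward, and 15 in hippocampus, 14 of them upward. Calls lost with an estimated correlation were MHC class II in cortex (adjusted p = 0.0716 with an estimated correlation) and, in hippocampus, MHC class II, cell cycle and monocyte markers (adjusted p = 0.118, 0.275 and 0.0764 with an estimated correlation). At an unadjusted p under 0.05 lay 1728 and 2569 genes. With RLE scaling the cortical comparison gave 69 higher and 95 lower genes. A fit of only the 2 cortical groups gave 271 genes, and 70 with replicate number as block. In hippocampus a fit of only 2 groups gave 125 genes, and leaving out CD11c-positive replicate 4 gave 129. Without cells carrying other cell types' markers 81 genes were called in cortex and 86 in hippocampus, and with genes per cell as a covariate 62 and 2. These groups too differ in the first number of their titles. Apoe and Sema4b changed by about as much between the cortical gates, which share these numbers, while for genes not called by the cortical gate a difference between possible library sets cannot be told apart from that of the groups.

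Region was compared within each kind of cell, a question the paired sampling of cortex and hippocampus poses. The first number in the titles parts the libraries by region as well, so a difference between possible library sets cannot be told apart from region. Transcripts of neurons and astrocytes were lower in hippocampal than in cortical libraries, and homeostatic genes were higher by camera, although these 3 calls were lost with an estimated correlation in WT cells, as was the homeostatic one in CD11c-negative APP cells. The neuron list stood at 997 ± 517 CPM in WT cortex and 48.3 ± 65.7 CPM in WT hippocampus. It stood at 776 ± 164 and 62.1 ± 43.5 CPM in CD11c-negative APP cells, and at 973 ± 251 and 100.2 ± 76.5 CPM in CD11c-positive APP cells. In WT cells 35 genes were higher and 208 lower in hippocampus. The kinesin gene Kif1a (ENSMUSG00000014602, chromosome 1, 93015464 to 93101951) was at least 402-fold lower (edgeR adjusted p = 0.0133), Arpp21 at least 358-fold, and the receptor phosphatase gene Ptprd at least 335-fold, all with 0 counts in hippocampus. Higher were the phospholipid enzyme gene Lpcat1 (1.09 ± 0.21, adjusted p = 0.00938), Plxdc2 (1.503 ± 0.290), Ythdf2 (0.93 ± 0.21), Cdk6 (1.04 ± 0.24), Dtx4 (1.71 ± 0.40) and the cohesin loader gene Nipbl (1.95 ± 0.49). Of the neuron list 3 members fell, 8 over the list alone (camera adjusted p = 4.28e-08, adjusted p = 0.0879 with an estimated correlation). Of the astrocyte list 4 fell (5.16e-05, adjusted p = 0.101 with an estimated correlation), and of the oligodendrocyte list 3 fell (6.39e-05). Homeostatic genes had 3 members higher (camera adjusted p = 3.26e-05, adjusted p = 0.101 with an estimated correlation). Camera also called DAM broad, cell cycle and lysosome upward (adjusted p = 0.264, 0.287 and 0.264 with an estimated correlation).

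In CD11c-negative APP cells 23 genes were higher and 318 lower in hippocampus. The secreted chaperone gene Clu was at least 265-fold lower (edgeR adjusted p = 0.00185), the synaptic fusion gene Snap25 at least 337-fold (adjusted p = 0.00628), the adhesion gene Ncam1 at least 293-fold, Arpp21 at least 264-fold, Kif1a at least 239-fold and Nrsn1 at least 170-fold. Higher were Tbc1d16 (4.70 ± 1.16), Map3k2 (5.44 ± 1.40), the nucleoside transporter gene Slc29a3 (1.87 ± 0.47), Slco2b1 (1.38 ± 0.35) and Ssh2 (1.23 ± 0.33). Neuron markers had 5 members lower, 8 over the list alone (camera adjusted p = 6.14e-11). Astrocyte markers had 2, 8 over the list alone (2.64e-09), and oligodendrocyte markers 0, 4 over the list alone (0.000489). These 3 lists passed with an estimated correlation. Homeostatic and lysosomal genes and DAM broad passed upward and lost the call (adjusted p = 0.129, 0.152 and 0.498 with an estimated correlation), as did ribosomal proteins (adjusted p = 0.147 with an estimated correlation). In CD11c-positive APP cells 33 genes were lower and 0 higher by edgeR. Among these were the growth factor gene Ptn (at least 526-fold, adjusted p = 0.00279), the axonal scaffold gene Ank3 (at least 383-fold), the glial transcription factor gene Sox9 (at least 601-fold), Golga7b (at least 747-fold), Arhgap44 (at least 402-fold) and the neural transcription factor gene Sox11 (at least 402-fold). Homeostatic genes had 0 members past the threshold, 6 higher over the list alone (camera adjusted p = 1.11e-13). Neuron markers had 1 lower, 8 over the list alone (1.11e-13), astrocyte markers 0, 8 over the list alone (3.41e-12), and oligodendrocyte markers 0, 1 over the list alone (1.75e-06). These 4 lists passed with an estimated correlation, whereas the interferon and lysosome lists did not (adjusted p = 0.224 and 0.224 with an estimated correlation). At an unadjusted p under 0.05 lay 3301, 2774 and 1675 genes in the 3 comparisons. In fits of only 2 groups edgeR called 0 genes in WT and 234 in CD11c-negative APP cells, and with the animal as block 0 and 0. Without cells carrying other cell types' markers it called 0, 55 and 0 genes in the 3 comparisons.

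The share of cells with transcripts of the DAM core list was measured next. It does not count cells in the full program, since the list has a baseline. In WT cortex its genes summed to 1124 ± 261 CPM, where Cst7 ran from 0 to 40.2 CPM and Igf1 from 0 to 0.61 CPM. A cluster led by DAM core members, described below, held 18 of 454 CD11c-negative APP and 12 of 390 WT cells of cortex. At least 2 of 1000 counts came from the list in 88.4 ± 1.55% of CD11c-positive and 22.4 ± 3.53% of CD11c-negative APP cortical cells, and in 77.9 ± 1.94% and 33.4 ± 4.80% of the hippocampal ones. Each difference had p = 0.0286, the smallest possible, by a 2-sided exact permutation test. The test took replicates as independent, although the titles of both gates name the same animals, so its p does not allow for the pairing. WT cells stood at 28.6 ± 4.76% in cortex and 25.5 ± 7.74% in hippocampus, and differences between CD11c-negative APP and WT cells did not pass (exact permutation p = 0.0857 and 0.143). Without thinning the hippocampal shares were 58.9 ± 2.73% and 42.3 ± 8.16% (exact permutation p = 0.0286), and without WT replicate 2 the thinned difference of 11.6 points passed as well. Apoe with at least 10 counts was present in 91.5 ± 1.93% of CD11c-positive and 10.8 ± 4.12% of CD11c-negative cortical APP cells, beside 10.1 ± 5.25% of WT cells. Neuron markers with at least 10 counts were present in 23.3 ± 11.3%, 17.3 ± 9.31% and 26.7 ± 6.74% of WT, CD11c-negative APP and CD11c-positive APP cortical cells and in 1.89 ± 1.90%, 2.12 ± 1.54% and 5.61 ± 4.03% of hippocampal cells. At equal depth Tmem119 was detected in 73.0 ± 9.35% of CD11c-negative APP and 49.0 ± 5.87% of WT hippocampal cells (exact permutation p = 0.0286). These APP cells also had more detected genes in all, and their replicate levels of Tmem119, 2175 to 2696 CPM, overlapped the 1873 to 2770 CPM of WT cells.

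**Figure D4:**
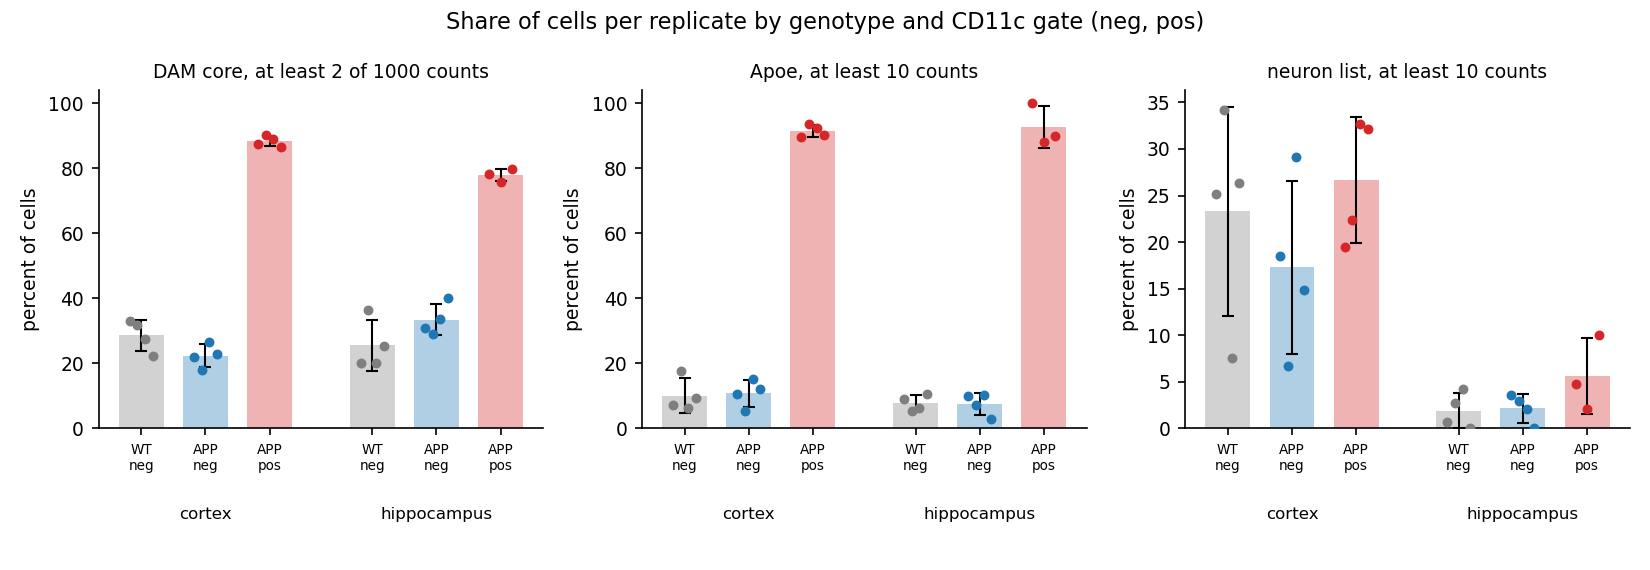
Percent of cells per replicate with at least 2 of 1000 counts from DAM core, at least 10 counts of Apoe and at least 10 counts of neuron markers, with bars for the mean, error bars for the SD and 1 point per replicate. Every CD11c-positive replicate lies above every CD11c-negative replicate of its region for DAM core and Apoe.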

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

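The effect of genotype on CD11c-negative cells differed between the regions, with 150 genes past the interaction test. Tests of a shared genotype effect, of gene length and of genes per cell were chosen after this result had been seen. Of the 226 genes called in hippocampus 24.8% had the same sign in cortex, which speaks against a shared effect. Most of them thus lay in the opposite direction in cortex, where no gene passed. Over the 3480 genes with at least 50 CPM the 2 effects correlated at a Pearson r of −0.030. Median genes per cell also differed in opposite directions between the regions. It was 839 ± 101 in APP and 596 ± 90.6 in WT hippocampus. In cortex it was 687 ± 127 in APP and 748 ± 58.3 in WT cells, with overlapping replicates. Without a trend over exon length the 226 kept 136% of their median signed log2 fold change (1.20 to 1.63, 213 still past) and the 150 kept 129% (1.53 to 1.97, 132 still past), which speaks against gene length as the whole cause. Genes per cell as a covariate left 87.7% for the 226 (1.20 to 1.05, median SE 0.223 to 0.289, 62 still past) and 87.2% for the 150 (1.53 to 1.34, median SE 0.274 to 0.340), of which 0 stayed past as folds fell and SE rose, so it may be part of the cause of the regional difference. A genotype effect particular to hippocampus, one of opposite direction in cortex and a difference between possible library sets, read from a number in the titles, cannot be told apart here, and grouping by the genotype tag called 0 genes in place of the 226.

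Neuron markers in CD11c-positive APP cortex stood at 599 CPM in replicate 1 against 1056 to 1127 CPM in the others, and their presence in cortical libraries was weighed with tests set before their results were seen. The 10% of cortical cells richest in them held 80.5% of the 32097 neuron marker counts, and 59.5% of 1431 cells held none. This share met the mark set beforehand against free RNA spread over all barcodes. That mark cannot decide, since the counts may be reads, so 1 captured molecule may give many counts in few cells. No other genes of similar level were compared. The 171 cells with at least 50 such counts kept 69.1% of the homeostatic share of the other cells (median 1.63% against 2.35%). This speaks against whole neural cells making up most of the 171, as far as the homeostatic list is particular to microglia, which was not tested. At least 50 homeostatic counts were held by 100% of them, a low bar at the depth of these cells, so it cannot tell neural cells from microglia. These cells had a median of 38152 counts against 18185 in the others, and Snap25 stood at 140, 125 and 188 CPM in the cortical and 15.2, 0 and 1.13 CPM in the hippocampal groups, although the CD11b and CD45 gate would exclude neurons. Whole neural cells as a part of the 171 are not excluded, nor is free RNA. Doublets and attached or engulfed neural material may remain as candidate sources, and these were not tested.

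Other single replicates lay far from their group. The mitochondrial share was 1.33% in CD11c-negative APP hippocampus replicate 2 against 1.11 to 1.13% in the others. Itgax stood at 31.8 CPM in the same replicate against 0 to 2.28 CPM, and at 3.66 CPM in WT hippocampus replicate 1 against 0. App stood at 332 CPM in CD11c-negative APP cortex replicate 4 against 26.4 to 72.6 CPM. Prnp stood at 1.69 CPM in WT hippocampus replicate 1 against 0. In WT hippocampus inflammatory genes reached 1296 CPM in replicate 3 against 950 to 980 CPM, ribosomal protein genes 14241 CPM in replicate 4 against 9542 to 10194 CPM, border-associated macrophage markers 67.3 CPM in replicate 2 against 119 to 129 CPM, and dendritic cell markers 16.8 CPM in replicate 3 against 0. In CD11c-negative APP cortex the Alzheimer risk genes summed to 9999 CPM in replicate 3 against 10687 to 10809 CPM, and neutrophil markers to 0.305 CPM in replicate 1 against 0. Astrocyte markers stood at 175 CPM in CD11c-negative APP hippocampus replicate 4 against 362 to 384 CPM. Red blood cell markers stood at 65.5 CPM in WT cortex replicate 3 against 0 to 0.637 CPM and at 280 CPM in CD11c-negative APP cortex replicate 2 against 0 to 0.61 CPM. In all 16 of 190 groups tested held such a replicate, and chance flags about 1 in 20 groups, here 9.5.

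The interferon list differed between the regions in the effect of the gate, with a camera adjusted p of 0.00726, 0.316 with an estimated correlation and 0.505 by fry.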

How the results depend on the processing

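Some results depended strongly on the processing, and for the shifts listed here the cause was not tested. Of the 182 counts of changed genes under alternatives other than leaving out a replicate, 102 lay within 1.5 times the reported count and 80 did not. A count of 0 that stayed 0 was taken as within. RLE scaling shifted the median of all genes by 0.11 for hippocampal genotype, −0.18 for the hippocampal gate, −0.12 for CD11c-positive against WT cortex, −0.12 for region in WT cells, 0.19 for the genotype interaction and −0.13 for the gate interaction, and split the hippocampal gate calls 41 to 37 and the CD11c-positive against WT cortex calls 69 to 95. Over all genes the naming rule covers, 258 pairs of gene and comparison past the threshold had 6264 values under alternatives, of which 4429 stayed past with their sign, 1820 were no longer past and 15 reversed in 14 pairs. The 1210 pairs not past had 28820 values, of which 25935 stayed so, 757 passed and 2128 reversed in 665 pairs. Folds are therefore given for a chosen part of the genes only. Depth, spread and replicate number, which were not varied apart, limit what can be called, and in simulated data with those of these samples 0% and 12% of genes with an 8-fold change were found for genotype and 14% and 6% for the gate, in cortex and hippocampus.

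DESeq2 called 245 and 1066 genes for genotype in cortex and hippocampus, 606 and 529 for the gate, 517 and 1215 for CD11c-positive against WT, 1601, 1160 and 652 for region in WT, CD11c-negative APP and CD11c-positive APP cells, and 790 and 248 for the genotype and gate interactions. With the replicate block as a random effect in limma voom, the same comparisons gave 19 and 413, 787 and 336, 618 and 993, 515, 563 and 761, and 233 and 18. With the replicate number as block in 2-group fits, hippocampal genotype gave 69 genes, CD11c-positive against WT cortex 70, and region 0 in WT and 0 in CD11c-negative APP cells, while cortical genotype stayed at 0 and the cortical gate gave 271. In list tests this blocked 2-group fit ended the 4 calls of cortical genotype and those of DAM broad and ribosomal proteins for region in CD11c-negative APP cells. Fits of only the 2 groups compared gave 99 for hippocampal genotype, 434 for the cortical gate, 271 and 125 for CD11c-positive against WT, and 0, 234 and 452 for region in WT, CD11c-negative APP and CD11c-positive APP cells.

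Without a gene filter cortical genotype gave 1 gene, region in CD11c-positive cells 78 and the gate interaction 2. With cells thinned to 1000 counts cortical genotype gave 1, the gate 316 and 183, CD11c-positive against WT cortex 315, and region in WT and CD11c-positive cells 19 and 13. Without cells of other types hippocampal genotype gave 84, the gate 68 and 12, CD11c-positive against WT 81 and 86, region 0, 55 and 0, and the genotype interaction 52. This setting removed 1239 of the 2657 cells, so fewer cells and fewer foreign transcripts cannot be told apart in these falls. Groups by the genotype tag gave 0 genes for hippocampal genotype, with Qars at −0.69, Picalm at 0.0078 and, in cortex, Lpl at −2.40. Without thinning the DAM core share of hippocampal CD11c-negative APP cells exceeded that of WT cells by 16.6 points (exact permutation p = 0.0286).

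Of the alternatives added after seeing the data, the number of cells with 5 counts gave 446 for hippocampal genotype, 930 and 581 for the gate, 818 and 936 for CD11c-positive against WT, 123 for region in WT cells, and 275 and 7 for the interactions. There Ctsb, Ctsd and Gm2a reversed in the cortical gate (−0.18, −0.39 and −0.25) and Ctsz and Ctsb in the hippocampal gate (−0.076 and −0.35). With genes per cell as a covariate the counts were 65 for hippocampal genotype, 39 and 24 for the gate, 62 and 2 for CD11c-positive against WT, 17 and 54 for region in WT and CD11c-positive cells, and 0 for the genotype interaction. With the gene length trend removed they were 21 for the hippocampal gate and 579, 127 and 54 for region. Equal weight per cell gave 11 and 0 for region in WT and CD11c-positive cells. Region gave 3, 151 and 0 without cells with 50 counts of other types and 2, 156 and 0 without clusters led by other markers. With counts under 5 set to 0 the gate interaction gave 2.

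Leaving out each replicate in turn kept 71 of 100 counts within 1.5 times and moved 29. Among those kept were the 8 of cortical genotype and the 15 of the gate interaction, where 0 stayed 0. The counts ran from 0 to 0 for cortical genotype and for the gate interaction, from 169 to 259 for hippocampal genotype and from 118 to 174 for the genotype interaction. The cortical gate ran from 115 without CD11c-positive replicate 1 to 145 and gave 116, 121 and 116 without CD11c-negative replicate 2 and CD11c-positive replicates 2 and 4. The hippocampal gate ran from 30 without CD11c-positive replicate 2-3 to 59 and gave 33, 38, 35 and 50 without CD11c-negative replicates 1 and 2 and CD11c-positive replicates 1-2 and 4. CD11c-positive against WT cortex ran from 80 without CD11c-positive replicate 4 to 135 and gave 100, 90 and 95 without WT replicates 1, 3 and 4 and 90, 96 and 103 without CD11c-positive replicates 1, 2 and 3. In hippocampus it ran from 129 without CD11c-positive replicate 4 to 296 and gave 145 without replicate 1-2. Region in WT cells ran from 96 without hippocampal replicate 2 to 324 and gave 111 and 123 without cortical replicates 2 and 4 and 139 and 111 without hippocampal replicates 3 and 4. In CD11c-negative APP cells it ran from 183 without hippocampal replicate 2 to 315. In CD11c-positive cells it ran from 7 without hippocampal replicate 2-3 to 30 and gave 21 and 20 without cortical replicates 3 and 4 and 8 and 11 without hippocampal replicates 1-2 and 4. The hippocampal DAM core share difference ran from 5.76 to 11.6 points and passed at the latter, without WT replicate 2.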

Other observations

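Sema4b was lower in hippocampal CD11c-negative APP cells (724 ± 49.8 CPM) than in WT cells (1518 ± 234 CPM), with a log2 fold change of −1.07 ± 0.18 (n = 4 and 4, edgeR adjusted p = 0.00113), and lower again in CD11c-positive cells. This gene lay outside the naming rule in that comparison and was chosen after its values were seen. Insig1 and Gm2a instead fell in CD11c-negative APP hippocampus and were higher in its CD11c-positive cells, where they stood at 723 and 3356 CPM. WT cells stood at 509 and 2964 CPM, and CD11c-positive against WT cells did not pass for either (edgeR adjusted p = 0.425 for Insig1 and 0.749 for Gm2a). The genotype and gate comparisons share the CD11c-negative APP hippocampal group.

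Clustering of all cells gave 5 clusters. A cluster of 800 cells was led by Cst7, Lpl, Apoe, Chst2, Lyz2 and Igf1, and 5 of its 10 leading genes were DAM core members. It held 463 of 587 CD11c-positive and 18 of 454 CD11c-negative APP cells of cortex, and 293 of 362 and 7 of 426 of hippocampus. Of WT cells it held 12 of 390 in cortex and 7 of 438 in hippocampus. A cluster of 147 cells was led by neural and astrocytic genes such as Map1b, Map2, Slc1a2 and Aldoc, and a cluster of 18 cells, 11 of them hippocampal CD11c-positive, by the MHC class II genes H2-Aa, H2-Ab1, Cd74 and H2-Eb1. The remaining clusters held 848 and 844 cells, with medians of 813.5 and 623.5 genes per cell. Of hippocampal CD11c-negative cells the first held 385 of 426 APP and 83 of 438 WT cells, and the second 25 APP and 344 WT cells. In cortex the first held 135 CD11c-negative APP and 178 WT cells, and the second 271 and 176. Whether genotype, genes per cell or possible library sets made this split was not tested.

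Whether the rise of DAM and ribosomal genes with the gate could follow gene length or the number of genes per cell was tested after the rise had been seen. The first measure, the share of the median fold left, was 69.97% in cortex and 81.3% in hippocampus for DAM genes and 51.3% and 64.1% for ribosomal genes without the length trend, and with genes per cell as a covariate 107% and 98.5% for DAM and 79.9% and 79.9% for ribosomal genes. As it left length undecided, the list test after correction was chosen next, with camera at the preset correlation. Its largest camera adjusted p was 1.58e-10 for DAM and 4.64e-10 for ribosomal genes without the length trend. With genes per cell it was 7.92e-12 for DAM and 1.96e-13 for ribosomal genes. Length may thus carry part of the rise, and both lists still rose beyond the fitted length trend. Median genes per cell did not overlap between the gates. CD11c-positive replicates ran from 903 to 1179 in cortex and 1053 to 1390 in hippocampus, CD11c-negative ones from 570 to 866 and 713 to 933. The covariate thus rests on spread within groups, so genes per cell cannot be excluded as the cause. No fit made both corrections together. Without the length trend, DAM members past the threshold went from 20 to 4 in cortex and from 14 to 4 in hippocampus, ribosomal ones from 14 and 7 to 0, all rising genes from 78 to 9 (median 1.47 to 0.86) and from 66 to 9 (1.70 to 1.29), and camera lost lysosome (adjusted p = 0.171) and inflammatory genes (0.0647) in cortex and MHC class I (0.0996) in hippocampus. Homeostatic genes instead fell further, from a median of −0.89 to −1.56 in cortex and from −0.70 to −0.96 in hippocampus. Rising and falling genes together went from a median size of 1.39 to 1.55 in cortex (109 of 183 still past) and from 1.71 to 1.47 in hippocampus (21 of 82). With genes per cell as a covariate DAM members past went from 20 to 7 and from 14 to 6 and ribosomal ones from 14 to 2 and from 7 to 1, where the median SE rose from 0.955 to 1.30 and from 0.815 to 1.36 for DAM members.

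Other splits of the samples were compared with the real groups, with the genotype results known beforehand. For genotype in hippocampus as many calls as the real 226 came from 1 of 35 splits, the real one, with 11 as the highest other. The gate gave 183 in cortex and 82 in hippocampus, where 1 of 35 splits reached as many and the highest others were 0 and 15. CD11c-positive against WT cells gave 160 and 309, reached by 1 of 35 splits each, with 0 and 68 as the highest others. Region gave 243, 341 and 33 in WT, CD11c-negative APP and CD11c-positive APP cells, reached by 1 of 35 each, with 10, 1 and 0 as the highest others. The genotype interaction gave 150, reached by 1 of 35, with 2 as the highest other. Where the real count was 0 every split gives as many, 35 of 35 for cortical genotype (highest other 0) and 100 of 100 for the gate interaction, so these comparisons say nothing about chance. The highest other of the gate interaction, 184, came from a split that exchanged the gate of 3 CD11c-positive and 3 CD11c-negative hippocampal replicates and kept that of cortex, a structure given by the gate itself.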
